A study of Homo sapiens with 4 samples.

How the data were processed

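TTchem-seq libraries of HCT116 cells were analysed, 2 of the DKO group and 2 of the WT group, grouped by their titles. Per the labels' protocols, cells were arrested with 2 µM palbociclib for 28 h, DKO cells received 500 µM auxin for 8 h, nascent RNA was labelled with 1 mM 4-thiouridine for 30 min, and 66 ng of labelled RNA entered a stranded library kit sequenced as single reads of 75 bp. The protocol text names auxin only for the DKO cells.

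The files that the authors deposited hold raw read counts per Ensembl gene, 1 library per file, with no header. Per the submitters' processing notes, STAR 2.7.3a and featureCounts 1.6 were used with genome build hg38. The gene set version, the strand setting and whether reads were counted over exons or whole gene bodies are not given in the sources used here. This matters for nascent RNA, where much of a long gene's signal is intronic, and without a known strand setting the reads of overlapping or antisense genes cannot be told apart. Near-identical genes, such as histones, ribosomal protein copies and HSPA1A with HSPA1B, are uncertain too, because reads may fit more than 1 copy. No spike-in was used here, so values are relative to the library total and a change in total transcription would not show.

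Each file lists 60656 IDs in the same order. A symbol was found for 42020 of them in a gene name table and a genomic span for 40517 in the RefSeq annotation of GRCh38.p14, which is the hg38 build. Of 19103 tested genes, 16021 had a symbol, 15909 a RefSeq match and 13178 were protein-coding. Counted reads totalled 51142867 to 53777749 per library, of which 99.941% to 99.945% lay in tested genes. Features without a symbol took 2.59% to 3% of reads and the largest feature 1.35% to 1.97%.

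The main test was the quasi-likelihood F-test of edgeR 4.0.16 in R 4.3.3, with group as the only term, TMM factors (0.992 to 1.005) and filterByExpr at its defaults (minimum count 10, minimum total 15). A gene was called at a Benjamini-Hochberg adjusted p under 0.05. The biological coefficient of variation was 3.46%. Log2 CPM used a prior count of 2. Gene lists, length bins, expression quartiles and chromosomes were tested with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01, beside camera with an estimated correlation and fry, and adjusted within each family. With an estimated correlation, camera has only the residual degrees of freedom that these few libraries leave. Failing it can therefore reflect low power alone. fry asks whether the genes of a set move one way on balance and does not compare the set with other genes. Length contrasts per library were compared by an exact two-sided permutation test over 6 splits.

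The design, the 26 gene lists and the rule for named genes were fixed before the data were examined. The rule takes every tested topoisomerase list member, the 6 largest rises and 6 largest falls among protein-coding genes with a mean log2 CPM of at least 3, an adjusted p under 0.05 and groups that do not overlap, up to 3 called members of each list that passed camera or had at least 3 called members, in its larger direction, and the 3 longest protein-coding genes called in each direction with a mean log2 CPM of at least 3. A member whose direction had 5 or fewer calls was named beyond it, after its value was seen. Some genes that the rule picks are not described here.

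The test was run on simulated data for DKO against WT, with counts drawn for the 19103 genes from the real means and library sizes. Of 50 genes changed at each fold size, 92% were recovered at 1.25-fold and 100% at 1.5-, 2- and 3-fold, and 10 of 18853 unchanged genes were called. A list shifted on purpose had a camera p of 2.24e-94 and an unchanged list 0.609. The changed genes and the shifted list were drawn only from genes above a floor of mean CPM, so recovery at low counts was not measured. In the simulation the libraries of a group vary at random, so it says nothing of differences shared by a whole group.

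Alternatives were DESeq2 size factors, total counts and upper quartile factors in place of TMM, no filter beyond 1 read, at least 50 reads in 2 libraries, the Wald test of DESeq2 1.42.0, limma voom, the replicate number as a block, protein-coding genes only, each library left out in turn, quintiles of span, and a slope on span with covariates. With a library left out, its lone partner is assumed to vary like the other group. A run without chromosome 20 genes was added after the chromosome medians were seen. The planned comparison of convergent with tandem neighbours needs gene strands and is not analysed here. GC content is not analysed here either, as no genome sequence was used. Figures were drawn with matplotlib 3.10.9.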

Results

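Nascent RNA was measured by TTchem-seq in HCT116 cells, a human colorectal carcinoma line. In this assay newly made RNA is labelled in living cells with a short pulse of 4-thiouridine, a modified uridine, chemically fragmented, purified and sequenced. The 4 libraries fall into 2 groups of 2. The DKO group carries both endogenous copies of TOP2A fused to an auxin-inducible degron, a tag that sends the protein for destruction when the plant hormone auxin is added, and has no intact TOP2B gene. These cells received 500 µM auxin for 8 h. The second group, called WT in the labels, stands for cells that retain both type II topoisomerases, the enzymes that pass one DNA duplex through another to relieve supercoils and tangles. All cells were held in G1 with 2 µM palbociclib, an inhibitor of the cell cycle kinases CDK4 and CDK6, for 28 h and pulsed with 1 mM 4-thiouridine for 30 min. No auxin is recorded for the WT libraries, so loss of the enzymes, auxin itself and any difference between the cell clones all separate the groups together. The comparison asks how transcription in G1 differs between cells without and with type II topoisomerases.

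The libraries were of even depth, with 53000795 and 53777749 counted reads in DKO and 51718468 and 51142867 in WT, and between 28386 and 28781 genes had reads in each. Replicates of a group correlated at r = 0.9969 (DKO) and 0.9966 (WT) on log2 CPM (counts scaled to library size), against 0.9864 to 0.9872 between groups. They differed by more than sampling noise, with a chi-square of 4.96 (DKO) and 4.25 (WT) per degree of freedom, so each was kept as a library of its own. The labels do not say whether replicates were separate cultures. P-values for single genes, like those of fry and the permutation test, thus rest only on the spread between these libraries. For single genes, edgeR largely pools that spread over genes. Its p-values can therefore be too small for a gene whose own replicates disagree. P-values of camera with the preset correlation compare genes with other genes under an assumed correlation, so they rest on genes rather than on libraries. Errors on log2 fold changes were derived from the edgeR F statistic with n = 2 per group, as the absolute log2 fold change over its square root. They are too small for large changes that rest on few counts, such as VSNL1 (41 and 54 counts in WT) and NCAM1 (8 and 4). They are also too small for well-counted genes whose replicates disagree, such as FOS and MT-ATP8. FOS stood at 27.2 and 18.6 CPM in WT with an error of 0.08. FAS, at 12.4 and 12 CPM in WT, had one of 0.07. MT-ATP8 stood at 227 and 165 CPM in WT with an error of 0.05. Adjusted p-values are Benjamini-Hochberg values from the quasi-likelihood test of edgeR unless another test is named.

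RNA of the edited genes was examined first. TOP2B RNA was 149 ± 1.8 CPM in DKO and 142 ± 2 CPM in WT (SD, n = 2), with 7852 and 8000 counts in DKO and 7264 and 7303 in WT. Its log2 fold change was 0.07 ± 0.05 (adjusted p = 0.223), so the gene's total count does not show the edit and the labels cannot be checked with it. An edit that stops the protein need not lower the gene's transcription. TOP2A, whose protein rather than RNA is removed by auxin, rose from 124 ± 2.4 to 166 ± 2.3 CPM, a log2 fold change of 0.42 ± 0.05 (adjusted p = 3.46e-15). Among the other topoisomerases and their repair partners, TDP1, which removes trapped topoisomerase I from DNA ends, rose by a log2 of 0.77 ± 0.05 (adjusted p = 1.49e-33). TOP1, the main nuclear type I topoisomerase, fell by 0.41 on the log2 scale (SE 0.05, adjusted p = 3.34e-12) and lies on chromosome 20, whose genes were lower as a whole. TOP1MT (log2 fold change -0.16, adjusted p = 0.0548), TOP3A (-0.11, 0.0668), TOP3B (-0.11, 0.161) and TDP2 (0.03, 0.727) did not pass the test. Without DKO replicate 1, TOP1MT passed it (-0.21, adjusted p = 0.0383), and its value was -0.08 without WT replicate 1 and -0.24 without WT replicate 2. As a list, these 8 genes, 2 higher and 1 lower, were not called (camera adjusted p = 0.55).

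Across the genome, 3632 of 19103 tested genes were higher and 4025 lower in DKO at an adjusted p under 0.05. With upper quartile factors the balance turned, with 4226 higher and 3328 lower. Most differences were small, with a median absolute log2 fold change of 0.36 among called genes. Rises outnumbered falls among large differences, with 615 genes over 2-fold higher against 254 over 2-fold lower, and 145 against 35 beyond 4-fold. The 6 largest rises among well-transcribed protein-coding genes were led by VSNL1, a neuronal calcium sensor, which went from 0.924 ± 0.19 to 108 ± 8.4 CPM (log2 fold change 6.86 ± 0.09, adjusted p = 7.15e-143). ZNF804A, a zinc finger gene, rose 35.8-fold (log2 5.16 ± 0.07) and LRMDA, a gene of melanocyte differentiation, 34.2-fold (5.09 ± 0.08). IAH1 rose 14.3-fold (3.84 ± 0.1), the tumour suppressor gene DLC1 14.3-fold (3.83 ± 0.08), and LRIG1, a negative regulator of growth factor receptors, 11.8-fold (3.56 ± 0.08). The annotation places IAH1 over part of ADAM17 and LRIG1 over part of SLC25A26, so reads of those pairs may be shared. VSNL1 lies on chromosome 2 from 17539972 to 17657018 and LRMDA spans 1130 kb of chromosome 10, from 75431624 to 76560168 (hg38).

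Falls were more modest. KRT80, an epithelial keratin, fell from 24.5 ± 1.8 to 6.31 ± 0.83 CPM (log2 fold change -1.96 ± 0.08, adjusted p = 1.66e-56), or 3.88-fold. BMP7, a secreted growth factor (-1.49 ± 0.05), and TGM2, a transglutaminase (-1.36 ± 0.08), followed, and both are on chromosome 20. The cell junction gene JCAD (-1.15 ± 0.05) and the monocarboxylate transporter gene SLC16A7 (-1.14 ± 0.05) fell by a little over 2-fold. For all of these genes the libraries of the groups did not overlap, which the rule that chose them required. The number of calls fell most with a WT library left out, when the spread within groups is taken from the DKO pair alone. Lost calls in those runs can come from that spread as well as from changed values. TOP2A, for 1, kept a log2 fold change of 0.443 without WT replicate 1 and 0.402 without WT replicate 2. Without WT replicate 1, 1023 genes were higher and 928 lower, and without WT replicate 2, 1467 and 1650.

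**Figure D1:**
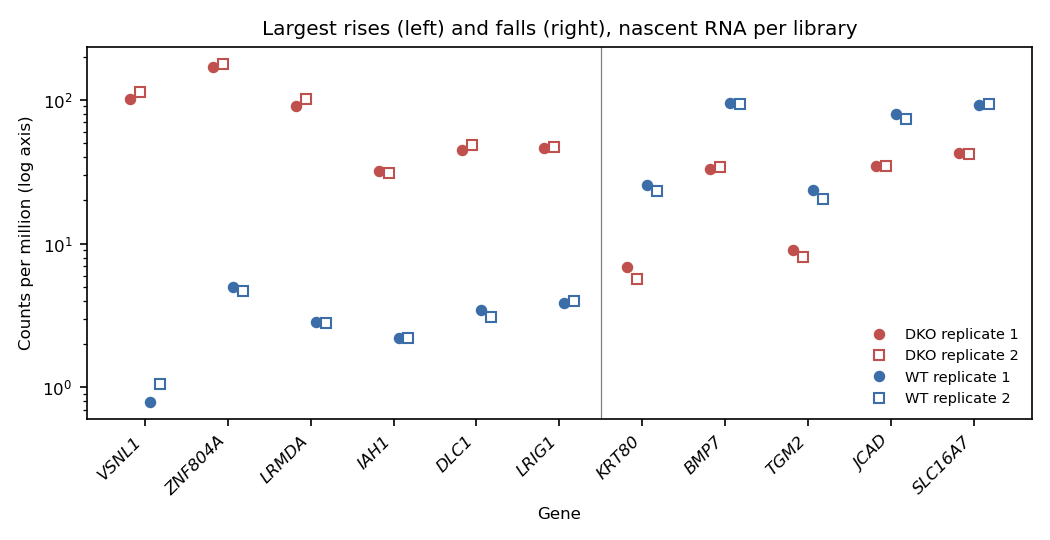
CPM (log axis) in each of the 4 libraries for the 6 protein-coding genes with the largest rises, left of the line, and 5 with large falls, right of it (red DKO, blue WT, filled replicate 1, open replicate 2). VSNL1 stands at 102 and 114 CPM in DKO against 0.791 and 1.06 in WT.

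Counts of called list members stand against 45.5% of all 13178 tested protein-coding genes called, 2677 higher and 3314 lower. Among 25 gene lists with tested members, all fixed before the data were examined, 10 differed from the other genes by camera with a preset correlation of 0.01 between genes, at an adjusted p under 0.05. With a correlation estimated from these data none of the 25 did, and the smallest adjusted p was 0.36. That setting leaves the test few degrees of freedom, so its failures do not tell correlated genes from low power. The neuronal list had an estimated correlation of -0.13, below the preset 0.01. Even so, its unadjusted camera p went from 6.16e-05 to 0.054. Targets of the aryl hydrocarbon receptor, a ligand-activated factor that switches on xenobiotic metabolism, rose in full, at 6 of 6 tested members and a median log2 fold change of 1.01 (camera adjusted p = 4.11e-11, and adjusted p = 0.36 with an estimated correlation). The cytochrome P450 gene CYP1B1 rose 4.24-fold (log2 2.09 ± 0.14), its relative CYP1A1 3.74-fold (1.9 ± 0.12), and TIPARP, which encodes a feedback inhibitor of the receptor, 2.68-fold, from 201 ± 5.9 to 537 ± 10 CPM (1.42 ± 0.05). These rises came in the group that received auxin.

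Genes of sterol synthesis fell together, with 21 of 24 tested members lower and none higher, and a median log2 fold change of -0.48 (camera adjusted p = 2.15e-18, and adjusted p = 0.36 with an estimated correlation). INSIG1, the sterol-regulated brake on cholesterol synthesis, fell from 82.2 ± 1.5 to 39.1 ± 0.58 CPM (log2 -1.07 ± 0.05). MVD, an enzyme of the mevalonate pathway (-0.89 ± 0.08), fell alike.

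Cell cycle genes moved in opposite directions. Of 32 tested E2F and G1/S genes, which serve entry into S phase, 21 fell and none rose (median -0.17, camera adjusted p = 6.75e-06, and adjusted p = 0.399 with an estimated correlation). The members with the largest falls were the transcription factor gene E2F1 (-0.77 ± 0.07), the replication clamp gene PCNA (-0.65 ± 0.05) and GINS1 of the replicative helicase (-0.64 ± 0.05), and all 3 are on chromosome 20. On other chromosomes 18 of 29 members fell, among them TK1 (-0.33), CDT1 (-0.3) and GINS2 (-0.28), picked after their values were seen. Without chromosome 20 the list kept its camera adjusted p under 0.05, at 0.000139. Of 29 tested G2/M genes, which act at mitosis, 16 rose (median 0.15, camera adjusted p = 0.00154, and adjusted p = 0.36 with an estimated correlation), led by PTTG1, the securin gene (0.43 ± 0.07), the kinetochore motor gene CENPE (0.43 ± 0.05) and HMMR (0.4 ± 0.06). Only AURKA, UBE2C and TPX2 of that list fell, again all on chromosome 20. Replication-dependent histone genes fell in 19 of 33 tested cases and rose in 3, H4C8, H3C6 and H3C1 (median -0.21, camera adjusted p = 0.00071, and adjusted p = 0.739 with an estimated correlation). H2BC18 (-0.69 ± 0.09), H2BC7 (-0.53 ± 0.1) and H4C4 (-0.49 ± 0.07) fell most, with uncertainty because histone genes have near-identical copies. Without DKO replicate 2 the histone list lost its call (median -0.13, adjusted p = 0.0696). Without WT replicate 1, CDT1, GINS2, H4C4, H4C8, TPX2, H3C6 and H3C1 missed the threshold (adjusted p of 0.052 to 0.224). TPX2 (0.0781), H3C6 (0.115) and H3C1 (0.172) also missed it without WT replicate 2, and H3C6 (0.0953) and H3C1 (0.217) without DKO replicate 1.

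Messenger and ribosomal RNAs of the mitochondrial genome were lower. All 15 tested members of that list fell (median -0.4, camera adjusted p = 7.06e-15, and adjusted p = 0.399 with an estimated correlation), with MT-ND1 at 1400 ± 2.4 CPM in DKO and 1950 ± 190 in WT (-0.48 ± 0.06), MT-ATP8 at -0.47 ± 0.05 and MT-CO1 at -0.45 ± 0.06. Mitochondrial tRNA genes, which are not in the list, were mixed. MT-TV (-1.21 ± 0.33), MT-TM (-0.52 ± 0.16), MT-TI (-0.35 ± 0.06) and MT-TD (-0.27 ± 0.1) were called lower and MT-TT higher (0.38 ± 0.08, adjusted p = 3.12e-05), while MT-TF, MT-TL1, MT-TQ, MT-TW, MT-TA, MT-TY, MT-TS1, MT-TE and MT-TP were not called. They were picked after their values were seen and not run with libraries left out. Mitochondrial genes took 3.86% and 3.56% of reads in DKO and 5.16% and 4.64% in WT. Cytosolic ribosomal protein genes rose slightly, 32 of 74 against 2 that fell, RPS21 on chromosome 20 and RPL14 (median 0.09, camera adjusted p = 0.00188, and adjusted p = 0.739 with an estimated correlation). RPS3A stood out with 0.73 ± 0.05, ahead of RPS19 (0.27 ± 0.05), and ribosomal protein genes have many processed copies that could take reads. Without DKO replicate 1 the ribosomal protein list was no longer called (median 0.05, adjusted p = 0.3), and without DKO replicate 2 its median was 0.14 (adjusted p = 4.15e-05). Without WT replicate 1, MT-ATP8 (log2 fold change -0.22, adjusted p = 0.0882), RPS19 (0.0559), RPS21 (0.0603) and RPL14 (0.208) missed the threshold, and RPL14 also without WT replicate 2 (0.273) or DKO replicate 2 (0.22).

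Markers of other cell types were tested because a clone can drift in identity. Neuronal markers had 3 of 7 tested members higher and none lower (median 0.19, camera adjusted p = 0.000308, and adjusted p = 0.36 with an estimated correlation). The adhesion gene NCAM1 went from 8 and 4 counts in WT to 170 and 155 in DKO (4.68 ± 0.27). The synaptic genes SNAP25, on chromosome 20 (2.97 ± 0.18), and SYT1, from 133 ± 2.4 to 549 ± 51 CPM (2.05 ± 0.05), also rose. Mesenchymal markers had 5 of 10 higher and 1 lower, the chromosome 20 gene SNAI1 (median 0.39, camera adjusted p = 0.0275, and adjusted p = 0.399 with an estimated correlation). TWIST1, a factor of mesenchymal identity, rose 8.49-fold (3.09 ± 0.16), while COL5A1 (1.44 ± 0.44) and SNAI2 (1.37 ± 0.4) rested on 6 to 30 counts per library. ZEB1 and ACTA2 completed the rises, and ACTA2 overlaps FAS, which also rose. Intestinal epithelial markers were not called as a list (camera adjusted p = 0.269), with 7 of 15 lower, including ELF3 (-0.63 ± 0.15), CLDN7 (-0.44 ± 0.17) and the adhesion gene CDH1 (-0.37 ± 0.05), and 1 higher, GRHL2. Of 6 immune cell markers, HLA-DRA rose and CSF1R fell (camera adjusted p = 0.596). Without WT replicate 1 the neuronal list (adjusted p = 0.0985) and the mesenchymal list (0.105) lost their calls, the latter also without WT replicate 2 (0.103) and with at least 50 reads required in 2 libraries (0.0501). With no count filter neither the neuronal (0.119) nor the mesenchymal list (0.0775) was called. The median of the neuronal list, which has few members, was unstable, at 0.04 without WT replicate 1, 0.1 without DKO replicate 1, 0.34 without DKO replicate 2, 0.36 without WT replicate 2 and 2.06 with at least 50 reads required. The mesenchymal median was 0.66 without DKO replicate 2. COL5A1, SNAI2, ACTA2, CLDN7, GRHL2, SNAI1 and CSF1R missed the threshold without either WT library in turn (adjusted p of 0.0542 to 0.253), and ELF3 (0.159) and HLA-DRA (0.0611) without WT replicate 1. Leaving out DKO replicate 1 ended the calls of SNAI2 (log2 0.85, adjusted p = 0.262), CLDN7 (-0.24, adjusted p = 0.361) and ACTA2 (0.0681), and leaving out DKO replicate 2 that of COL5A1 (0.158).

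Stress and signalling lists went both ways and were not called by camera in the planned setting. Of 28 p53 targets 10 rose, with the cytokine gene GDF15 (0.86 ± 0.07), the death receptor gene FAS (0.85 ± 0.07) and PLK2 (0.59 ± 0.05) ahead, and PHLDA3, PLK3, FDXR and ZMAT3 fell (camera adjusted p = 0.057). With DESeq2 size factors that list passed camera at 0.0487 and with upper quartile factors at 0.04, and fry called it (adjusted p = 0.0235). Immediate early genes split into 9 higher and 14 lower of 30 (adjusted p = 0.279, and 0.045 without DKO replicate 1). The AP-1 genes FOS (-0.91 ± 0.08) and FOSB (-0.86 ± 0.1) and the factor KLF2 (-0.79 ± 0.08) were the members with the largest falls. Without WT replicate 1, FOS (-0.6, adjusted p = 0.0949) and FOSB (-0.54, adjusted p = 0.294) were smaller and not called, and KLF2 (-0.76) then exceeded both. FOSB was also -0.54 without DKO replicate 2. Integrated stress response genes had 9 of 24 higher, with the cystine transporter gene SLC7A11 (0.81 ± 0.05), the serine synthesis gene PHGDH (0.7 ± 0.05) and CHAC1 (0.61 ± 0.12) ahead, and 5 lower, namely CEBPB and TRIB3 on chromosome 20, DDIT4, PPP1R15A and ATF5 (adjusted p = 0.167, but 0.0316 without DKO replicate 2 and 0.0308 without chromosome 20 genes). Of 25 hypoxia and glycolysis genes 8 rose, including NDRG1 (1.07 ± 0.05), KDM3A (0.56 ± 0.05) and SLC2A3 (0.49 ± 0.13), and 6 fell (adjusted p = 0.294). Their median was -0.03 although camera's direction was up, and it turned to 0.002 with upper quartile factors. PHLDA3, PLK3, FDXR, ZMAT3, PPP1R15A, TRIB3, ATF5 and SLC2A3 each missed the threshold without WT replicate 1 (adjusted p of 0.0606 to 0.774). All of these but PHLDA3 and PLK3 also missed it without WT replicate 2 (0.0504 to 0.274), FDXR (0.256) and SLC2A3 (log2 0.32, adjusted p = 0.0953) without DKO replicate 1, and ZMAT3 (0.188) and ATF5 (0.321) without DKO replicate 2.

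Wnt and beta-catenin targets, active in this tumour type, had 9 of 15 members higher and 5 lower (camera adjusted p = 0.318). AXIN2, a feedback inhibitor of the pathway, rose 2.91-fold (1.54 ± 0.08), with NOTUM (0.97 ± 0.24) and BAMBI (0.69 ± 0.09) next. TNFRSF19 (-1.37), EPHB3 (-0.93), DKK1 (-0.71), EPHB2 (-0.53) and CCND1 (-0.34) fell. Interferon-stimulated genes had 6 of 25 higher, with EPSTI1 (1.41 ± 0.19), RSAD2 (0.89 ± 0.16) and HERC5 (0.66 ± 0.07) ahead, and IFIT1, IFI6 and OASL lower (adjusted p = 0.269). NF-kB targets had TRAF1 (0.95 ± 0.3), NFKB1 (0.34 ± 0.05) and CD83 (0.23 ± 0.09) higher and TNFAIP2, NFKB2 and RELB lower of 16 (adjusted p = 0.832). Heat shock genes had HSPA1B (-0.89 ± 0.27), DNAJB1 (-0.35 ± 0.05), SERPINH1 (-0.3 ± 0.07) and DNAJA1 lower and HSPA4L higher of 18 (adjusted p = 0.368), and HSPA1B has a near-identical neighbour. Without WT replicate 1 the calls of NOTUM, CCND1, RSAD2, IFI6, OASL, TRAF1, CD83, NFKB2, RELB, HSPA1B, DNAJB1, SERPINH1 and DNAJA1 were lost (adjusted p of 0.0581 to 0.371). Without WT replicate 2 those of NOTUM, IFIT1, IFI6, OASL, TRAF1, CD83, RELB, SERPINH1 and DNAJA1 were lost (0.0646 to 0.353). Without DKO replicate 1 IFI6, OASL, CD83, NFKB2 and HSPA1B were not called (0.0547 to 0.327), and without DKO replicate 2 NOTUM, IFI6, TRAF1 and DNAJA1 were not (0.0584 to 0.379). HSPA1B shrank to -0.445 without WT replicate 1, TRAF1 to 0.62 without WT replicate 2, and NOTUM to 0.59 and SERPINH1 to -0.19 without DKO replicate 2.

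Genes of the chromatin and transcription machinery were examined next. Of 22 cohesin, condensin and CTCF genes, SMC4 (0.31 ± 0.05), RAD21 (0.3 ± 0.05), NIPBL (0.19 ± 0.05), PDS5B and STAG2 rose and none fell (camera adjusted p = 0.302). RNA polymerase II and elongation factors had 13 of 33 lower, including NELFCD on chromosome 20 (-0.53 ± 0.05), HEXIM1, an inhibitor of the elongation kinase (-0.5 ± 0.07), and POLR2G (-0.31 ± 0.09), and 5 higher, among them CDC73, ELL2, POLR2A and CTR9 (adjusted p = 0.313). Genes named ZNF, mostly zinc finger repressors, had 132 of 404 lower and 46 higher (median -0.09, camera adjusted p = 0.0375, and adjusted p = 0.739 with an estimated correlation). ZNF426 (-1.85 ± 0.31), ZNF80 (-1.76 ± 0.43) and ZNF45-AS1 (-1.29 ± 0.39) had the largest falls, all at 50 counts or fewer per library, and ZNF45-AS1 overlaps ZNF45. The ZNF call was lost without DKO replicate 2 (0.513), without WT replicate 2 (0.0506), with at least 50 reads required in 2 libraries (0.0744) and with protein-coding genes only (0.151). HOX genes had 9 of 25 higher and none lower (camera adjusted p = 0.0588, and adjusted p = 0.0229 by fry). HOXA-AS3 (1 ± 0.21), HOXD-AS2 (0.88 ± 0.24) and HOXD3 (0.85 ± 0.12) were ahead, and HOXA-AS3 overlaps several HOXA genes. The HOX list passed without WT replicate 1 (0.0222) and without WT replicate 2 (0.0339). The 60 clustered protocadherin genes had at most 7 reads in any library and none was tested. Of the members named here, NIPBL, PDS5B, STAG2, POLR2A, ZNF80, ZNF45-AS1 and HOXD-AS2 missed the threshold without either WT library (0.0569 to 0.552). ZNF80 was -1.13 without WT replicate 2. POLR2G (log2 -0.19, adjusted p = 0.204), CTR9 (0.0903) and ELL2 (0.0531) did so without WT replicate 1 and HOXA-AS3 (0.0824) without WT replicate 2, as did PDS5B (0.0938) and STAG2 (0.36) without DKO replicate 2.

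Adjusted over the list alone, the counts were the same for 17 of the 25 lists. In the other 8 they became 2 higher and 3 lower for topoisomerases, 12 and 4 for p53 targets, 9 and 15 for immediate early genes, 17 and 3 for G2/M genes, 10 and 6 for the integrated stress response, 33 and 2 for ribosomal proteins, 4 and 0 for cohesin and condensin, and 47 and 136 for ZNF genes. Members named beyond the rule because 5 or fewer were called in a direction were picked after their values were seen.

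**Figure D2:**
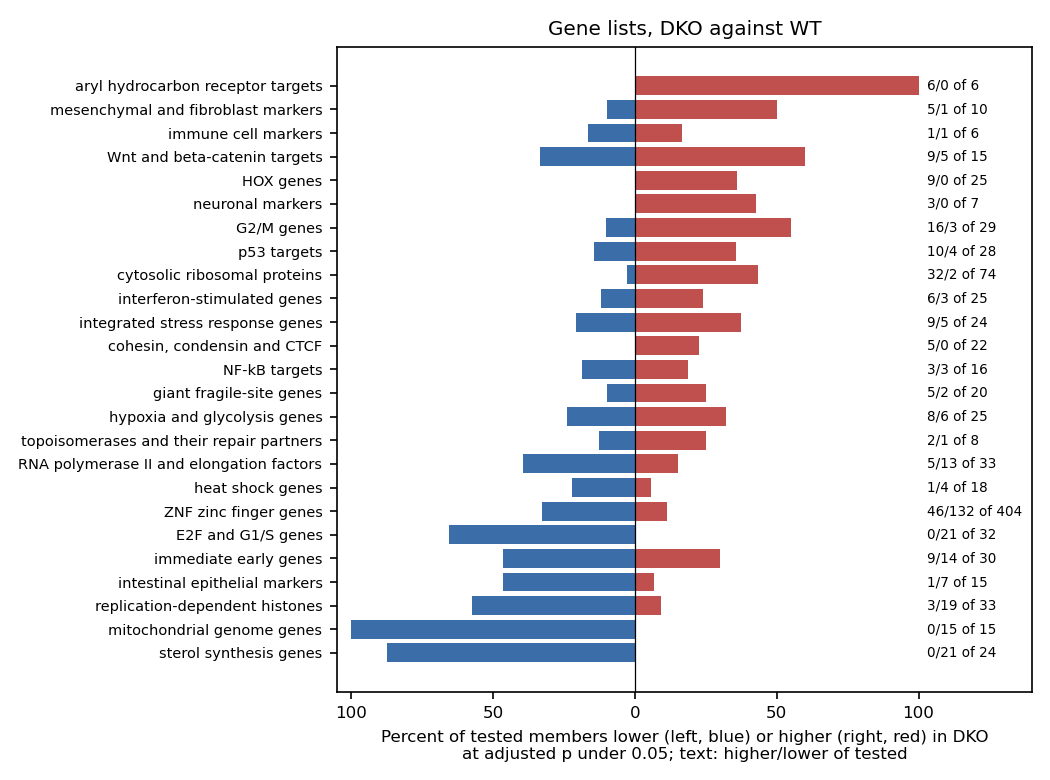
Percent of tested members of each gene list that were higher (red, right) or lower (blue, left) in DKO at an adjusted p under 0.05 by edgeR, with counts at the right edge, ordered by median log2 fold change. Aryl hydrocarbon receptor targets stand at the top with 6 of 6 higher, and sterol synthesis genes at the bottom with 21 of 24 lower.

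Type II topoisomerases act on the supercoils that transcription makes, so change was set against gene length. Long genes were higher and short genes lower in DKO. Genes under 10 kb had a median log2 fold change of -0.12, with 723 of 2325 lower and 247 higher, and genes of 10 to 30 kb one of -0.07. The median was near 0 from 30 to 100 kb, 0.06 from 100 to 300 kb, and 0.11 over 300 kb, where 250 of 684 genes were higher and 99 lower. Over 2-fold rises made up 8.48% of genes over 300 kb and 1.85% of genes under 10 kb, and over 2-fold falls 1.61% and 1.08%. By camera with the preset correlation, 4 of the 5 bins differed from the other genes (adjusted p = 0.00178, 0.00268, 0.862, 0.000824 and 6.27e-06 from short to long), and with an estimated correlation none did (lowest adjusted p = 0.662). Nor was any bin called by fry (lowest adjusted p = 0.16). Without DKO replicate 2 the bins under 10 kb (0.0718), from 10 to 30 kb (0.0524) and from 100 to 300 kb (0.0524) were no longer called, and the last had a median of 0.03.

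The longest genes did not all follow this trend. Among the longest well-transcribed genes (mean log2 CPM of at least 3) that rose, MACROD2 spans 2060 kb of chromosome 20 (13995516 to 16053197, hg38) and went from 7.18 ± 0.09 to 56.8 ± 2 CPM (2.98 ± 0.07), against the fall of most genes of that chromosome. CCSER1, 1480 kb long, rose by a log2 of 0.63 ± 0.05. Of the 3 longest such genes that fell, GALNT13 changed by -0.32 ± 0.09, NAALADL2 by -0.72 ± 0.05 and ANKS1B by -0.59 ± 0.09, with spans of 1390, 1370 and 1250 kb. In the list of giant fragile-site genes, 5 of 20 rose, among them CNTNAP2 (1.6 ± 0.15) and PDE4D (0.71 ± 0.11), and NAALADL2 and IMMP2L fell (camera adjusted p = 0.233, and 0.0101 without DKO replicate 1). The list's median was -0.02 although camera's direction was up, and turned positive with upper quartile factors (0.01), without DKO replicate 1 (0.05) and without WT replicate 2 (0.04). GALNT13 was not called without DKO replicate 1 (log2 -0.19, adjusted p = 0.137), WT replicate 1 (0.206) or WT replicate 2 (0.135), nor was IMMP2L (0.0513) without WT replicate 1.

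Each library was also given a single contrast, the mean log2 CPM of 2844 genes over 100 kb minus that of 5996 genes under 30 kb. It was 1.973 and 2.059 in DKO and 1.762 and 1.831 in WT, so the group means differed by 0.219 with SDs of 0.061 and 0.049. Both DKO libraries lay above both WT libraries. The exact two-sided permutation p was 0.333, which is the smallest that 2 against 2 libraries can give. Across 13178 genes the log2 fold change rose by 0.155 per 10-fold span, and by 0.17 with expression and chromosome as covariates (Spearman correlation 0.25 across genes, which are not independent replicates).

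**Figure D3:**
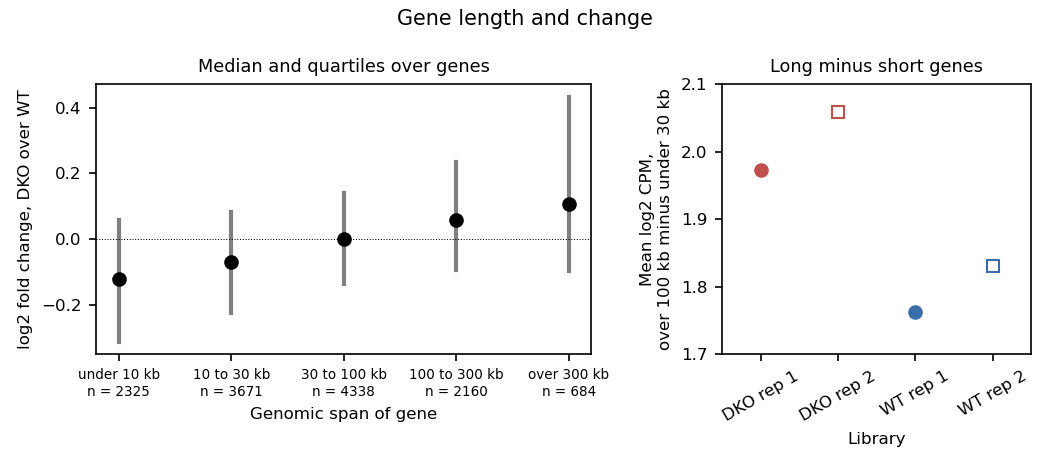
Left, median (dot) and quartiles (bar) of the log2 fold change of DKO over WT for protein-coding genes in 5 bins of genomic span, and right, mean log2 CPM of genes over 100 kb minus that of genes under 30 kb in each library, on an axis that does not start at 0. The median goes from -0.12 under 10 kb to 0.11 over 300 kb, and both DKO libraries (1.973 and 2.059) lie above both WT libraries (1.762 and 1.831).

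Genes were also divided by their level of transcription. Medians over quartiles of mean log2 CPM, from low to high, were 0, -0.1, -0.05 and 0.03, and only quartile 2 was called by camera (adjusted p = 0.0279, and adjusted p = 0.547 with an estimated correlation). No quartile was called by fry (adjusted p = 0.16 each). In quartile 2, 1143 of 3294 genes were lower and 521 higher, and in quartile 4, 963 of 3295 were higher and 624 lower. The call for quartile 2 ended without DKO replicate 1 (0.0891), without DKO replicate 2 (0.316), with no count filter (0.217) and with protein-coding genes only (0.0609). Quartile 3 passed without WT replicate 2 (0.0436), and quartile 4 passed without WT replicate 2 (0.00178), with DESeq2 size factors (0.0458) and with upper quartile factors (0.00785).

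Chromosome 20 stood apart from every other chromosome. Of its 430 tested genes 342 were lower and 13 higher, and 91.9% had a log2 fold change below 0. The median was -0.59 (camera adjusted p = 3.62e-63, adjusted p = 0.147 with an estimated correlation, and adjusted p = 0.0115 by fry), and the other scalings, filters, gene selections and left-out libraries kept it between -0.609 and -0.549. All 7 windows of 10 Mb along it had medians from -0.717 to -0.413. The median of no other chromosome exceeded 0.13 in size. Chromosomes 19 (-0.13), 22 (-0.08), 4 (0.08) and 18 (0.11) passed camera with the preset correlation (adjusted p = 0.000706, 0.0427, 0.000825 and 0.00482) and none did with an estimated one (adjusted p = 0.57 each). None of them was called by fry either (adjusted p = 0.0922, 0.0922, 0.0666 and 0.0922). Chromosome 22 was not called without DKO replicate 1 (0.0632) or DKO replicate 2 (0.218), with protein-coding genes only (0.1) or with the replicate number as a block (0.151). Chromosome 16 was called without WT replicate 1 (0.0467) and with no count filter (0.0401). Without WT replicate 2, chromosomes 16 (0.0194) and 17 (0.0141) were called.

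**Figure D4:**
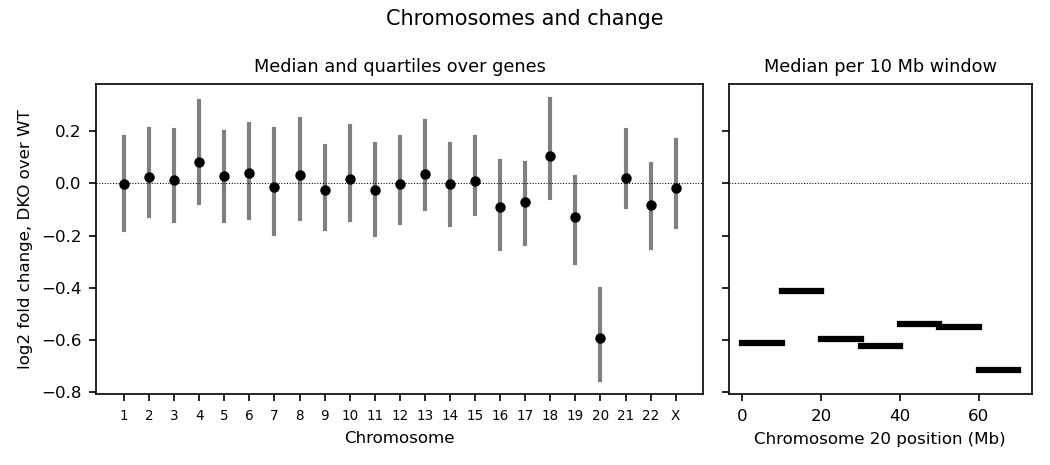
Left, median (dot) and quartiles (bar) of the log2 fold change of DKO over WT for tested genes of each chromosome, and right, the median in each 10 Mb window of chromosome 20. Chromosome 20 has a median of -0.59, and its windows run from -0.717 to -0.413.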

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

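The run without chromosome 20 genes was chosen after the data were seen, and the other settings before. No result changed to a called effect in the opposite direction under any setting. TOP2A stayed called and TOP2B uncalled throughout, chromosome 20 and genes over 300 kb stayed called wherever camera used the preset correlation but not with an estimated one (adjusted p = 0.147 and 0.662), and the slope on span stayed positive. By fry, chromosome 20 was called (adjusted p = 0.0115) and genes over 300 kb were not (adjusted p = 0.16). The counts of 3632 higher and 4025 lower genes became 1640 and 1655 with no filter, and 2346 and 2466 by the DESeq2 Wald test. With upper quartile factors these counts were 4226 and 3328, so more genes were then higher than lower. They ranged from 1023 to 3127 and from 928 to 3443 over the runs that each left out 1 library, lowest without WT replicate 1. Of the 10 lists called, 0 stayed called with an estimated correlation, where the test has few degrees of freedom. By fry 8 lists were called, 6 of them among the 10. Histone, ribosomal protein, mitochondrial genome and ZNF lists were not called by fry (adjusted p = 0.151, 0.259, 0.11 and 0.268). With libraries left out, medians ranged from -0.156 to -0.091 under 10 kb, from -0.086 to -0.055 at 10 to 30 kb, and from 0.029 to 0.083 at 100 to 300 kb. Those of the expression quartiles ranged from -0.131 to -0.077 (quartile 2), -0.054 to -0.038 (quartile 3) and 0.019 to 0.043 (quartile 4). Quartile 4 passed the threshold at 0.039 with DESeq2 size factors, 0.066 with upper quartile factors, 0.045 with at least 50 reads, 0.046 with protein-coding genes only and 0.03 without chromosome 20. Quartile 2 lost its call at -0.071 with no filter and -0.082 with protein-coding genes only, and quartile 3 gained one at -0.076 with no filter. The cause of these changes was not tested.

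The replicate numbers are not said to mark a shared batch, and over all genes the deviations of same-numbered libraries correlated at 0.0114. In both groups, though, replicate 2 had the larger long minus short contrast and the smaller mitochondrial share, so whether the numbers pair the libraries stays open. With the replicate number as a block, 3742 genes were higher and 4078 lower, quartile 2 (-0.096, adjusted p = 0.106) and the ZNF list (adjusted p = 0.174) were not called, and 4 chromosomes were called in place of 5. Of the genes run under the alternatives, FDXR alone lost its call with the block (log2 fold change -0.173, adjusted p = 0.0596). Of 150 genes run under the alternatives, 61 lost a call under at least 1 of them, 58 of them without WT replicate 1 and 41 with no filter. DESeq2 gave no adjusted p for some genes of few counts, which are left out. Genes of many counts such as NIPBL, RPS19 and MT-ATP8 were among those that lost a call, as were genes of few counts such as COL5A1 and ZNF80. The comparison of neighbour orientations and its gap settings were not run.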

Other observations

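Of 2069 tested long non-coding RNAs, 400 were higher and 281 lower in DKO, with a median log2 fold change of 0.07, against -0.03 for protein-coding genes, of which 2677 of 13178 were higher and 3314 lower. Features without a RefSeq match had 484 of 3194 higher and 338 lower (median 0.075), and no difference between these classes was tested. LINC02331 on chromosome 14 went from 11.1 to 402 CPM (log2 5.17 ± 0.06, adjusted p = 2.25e-150 by edgeR) and MIR181A1HG on chromosome 1 from 118 to 371 CPM (1.66 ± 0.05). LINC00640, also on chromosome 14, fell from 34 to 4.29 CPM (-2.98 ± 0.08) and MIR3659HG from 18.9 to 4.52 CPM (-2.06 ± 0.09). These genes were picked after their values were seen. Protein-coding genes over 4-fold higher, 102 in number, had a median span of 101 kb, against 35 kb for all tested protein-coding genes, and 51 of them exceeded 100 kb. The 14 over 4-fold lower had a median span of 78.9 kb, and 6 exceeded 100 kb. Of 291 windows of 10 Mb with at least 10 tested genes, none off chromosome 20 had a median below -0.25. Off it, 5 had one above 0.25, among them 2 adjoining windows of chromosome 1, from 180 to 190 Mb (median 0.282, 26 of 41 genes higher and 0 lower) and from 190 to 200 Mb (0.372, 11 of 15 higher). All 5 were windows of few tested genes, 15 to 41 each. The 2 on chromosome 1 were picked after their values were seen, and no single window was tested.

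In the patterns weighed here, the tests of copy number, of length without chromosome 20, of the mitochondrial share and of auxin were chosen after the results were seen, and the test with matched gene sets before its result was seen. Chromosome 20 genes were lower in DKO with a median of -0.594 (bootstrap over genes -0.623 to -0.564), and libraries of a group were alike, with median deviations of -0.29 and -0.304 in DKO and 0.291 and 0.289 in WT. Span and expression of its genes do not account for this, since among 1000 sets of genes from other chromosomes matched on both, the lowest median was -0.05. A difference in copy number between the lines, fewer in DKO or more in WT, is a candidate explanation, as every window with at least 20 genes was shifted, the least shifted to -0.413, and the log2 of 2 copies over 3 is -0.585. DNA was not analysed here, so an effect of topoisomerase loss on this chromosome stays open. Genes such as TOP1 (-0.407, less lowered than 74.7% of the chromosome's genes), E2F1 and PCNA carry this shift, while PAK5 (3.15), MACROD2 (2.98), SNAP25 (2.97), SLC12A5 (1.9, not called without WT replicate 2, adjusted p = 0.0694) and JAG1 (0.6) rose against it.

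Long genes were higher and short genes lower in DKO, and chromosome 20 does not account for it, since the median over 300 kb minus that under 10 kb was 0.228 with that chromosome and 0.223 without it. A second explanation is an axis between libraries, of unknown origin, that also goes with the share of mitochondrial reads. Within each group the library with the smaller mitochondrial share had the larger long minus short contrast, by 0.086 in DKO and 0.07 in WT, replicate 2 in both, and across 9147 genes the replicate differences followed span with a Spearman correlation of 0.527 and 0.29, against 0.256 for DKO minus WT. A rank correlation does not measure the size of a trend. Slopes per 10-fold span were 0.0472 and 0.1071 in the DKO libraries and -0.1019 and -0.0524 in the WT libraries. By that measure the groups lay further apart than the replicates. Ribosomal protein genes went with the mitochondrial share within groups (median deviations of 0.091 and -0.002 in DKO and -0.021 and -0.069 in WT) but against it between groups, where that list was not called without DKO replicate 1. With that share as a covariate the group difference of 0.219 became -0.004 ± 0.058, with 1 residual degree of freedom and a 95% interval from -0.74 to 0.73, so an effect of topoisomerase loss and this axis cannot be told apart with 4 libraries.

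Aryl hydrocarbon receptor targets had a median log2 fold change of 1.014 in DKO, above each of 10000 random lists of 6 genes matched on expression, whose highest median was 0.693. Such lists treat genes as independent, and the camera adjusted p was 0.36 with an estimated correlation, where the test has few degrees of freedom. Auxins can be indoles, and indoles can bind this receptor, so a response to auxin itself may account for the rise. No WT library is recorded as given auxin (0 of 2), so auxin and loss of the topoisomerases cannot be told apart, and the same limit holds for every difference between the groups.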
